A study of Mus musculus with 11 samples.

How the data were processed

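Transcripts were measured with the GeoMx digital spatial profiling platform, in which barcoded probes hybridised to a tissue section are released by ultraviolet light from a chosen area and sequenced. Per the labels' protocols, sections of frozen mammary gland, fixed in paraformaldehyde and taken from 3 mice, were hybridised with the NanoString Whole Transcriptome Atlas probes for mouse and stained for smooth muscle actin (SMA), podoplanin (Pdpn) and DNA. Regions were chosen by the SMA and Pdpn stains, and within each region the cells positive for ZsGreen, the lineage reporter of periostin expression, were segmented and collected. The labels count 12 collected areas. The 11 with a label and a column were analysed here, 6 labelled Pdpn-adjacent (regions 2, 3, 4, 7, 8 and 11) and 5 labelled SMA-adjacent (regions 1, 5, 6, 9 and 10). The labels do not tie a region to a mouse, and each group holds more regions than there were mice, so some regions share a mouse. Every p-value over regions treats them as independent and can be too small. It can be too large where a mouse gave regions to both groups, which the labels do not tell.

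The deposited table holds raw counts per probe for each region, with no normalization, judged from its values: whole numbers whose totals differ widely between columns. It holds 19965 endogenous probes and 210 negative-control probes, and 3 targets have 2 probes each, which were kept apart. No value is 0 and the lowest is 1. Whether 1 was added to each count or zeros were raised to 1 is not given in the sources used here, nor are the steps from reads to counts and the removal of duplicate reads. Probe positions are on GRCm38.p6, per the file headers, and 19884 endogenous probes have a position there, some of them several. A position printed beside a gene is the target site of its probe, not the extent of the gene. Gene identifiers were present for 19954 probes, and 19910 of them matched the RefSeq gene table, which was used for names only. A probe that matches several genes or sites was reported without a position.

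Background was taken from the 210 negative-control probes, as their geometric mean count in each region, and levels over background are counts divided by it. A probe was counted as above the floor of a region when its count exceeded the mean plus 2 SDs of the negative probes on the log2 scale. The share of counts above background is the share left after the mean of the negative probes was taken from each endogenous probe's part of the total. Negative probes were left out of library sizes and tests. Their summed counts came to between 0.610% and 0.979% of all counts of a region, endogenous and negative probes together.

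Probes kept by filterByExpr of edgeR 4.0.16 (19935) were tested between the groups in R 4.3.3. Library sizes were scaled by TMM factors and the quasi-likelihood test of edgeR was used, two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Each log2 fold change is Pdpn-adjacent minus SMA-adjacent, and its standard error (SE) is the one implied by the test's p. Levels are given as CPM, counts scaled to a common TMM-adjusted library size. The 26 gene lists covered cell types next to the segments, fibroblast states, extracellular matrix, signalling and cell states. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, which asks whether a list's genes move relative to all other genes, and again with an estimated correlation and with fry. Each list's median log2 fold change was also ranked among 10000 random lists of the same size matched on mean CPM. Single measures per region were compared with exact two-sided permutation tests over all 462 ways to choose the groups, whose smallest possible p is 0.00216. Principal components were computed from log2 CPM with a prior count of 2, centred per gene.

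The groups, the tests, the lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. Results of 3 genes, 1 of them past the threshold, are not reported here. The rule named Postn, Pdpn and Acta2, the 10 genes of largest change in each direction past the threshold, the 5 of smallest p in a direction where fewer than 5 passed, up to 4 members of smallest p from each list with a called gene or a camera call, and 6 genes chosen beforehand for a role in lymphatic vessels or matrix. That set left out each region in turn, changed the filter, the scaling or the test tool (DESeq2 1.42.0, limma-voom, limma with array weights, robust spread), or added the negative-probe level or the region number as a covariate. Alternatives chosen after seeing the data left out regions 2 and 11, regions 2, 3 and 11, regions 4 and 8, or regions 3 and 7, scaled libraries by their negative probes, subtracted background in the 8 libraries above 100000 counts, or added the share of counts above background as a covariate.

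The tests were tested on simulated data drawn from the means and library sizes of the real regions (19927 genes tested, 200 changed, dispersion 0.025). For the simulated comparison of Pdpn-adjacent with SMA-adjacent regions, 88% of the 50 genes raised by a log2 fold change of 1 and 64% of the 50 lowered by that amount were recovered, as were 100% of those changed by 2 in either direction, with 16 false calls. The shifted list was called and 0 of 25 unshifted lists were. Each simulated gene had the same dispersion, and the regions held no other structure. The recovery therefore does not describe real genes that vary more between regions. In the real data Acta2 and Myh11, with log2 fold changes of -2.77 and -2.51, did not pass. The simulated genes varied independently of each other, so this cannot show how the list test behaves where members vary together. In the real lists the estimated correlation between members reached 0.876 (skeletal muscle). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Total counts of endogenous probes ran from 22757 to 3086323 per region, so the precision differed widely, and in the smallest libraries most probes held the lowest value.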

Results

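The series profiled periostin-lineage cells of the naive mouse mammary gland in place. Periostin (Postn) is a secreted matrix protein made by stromal cells, and the mice carried a ZsGreen reporter that marks cells that express or once expressed it. The question was how such cells near lymphatic vessels, marked by podoplanin, differ in their transcripts from those near blood vessels and ducts, marked by smooth muscle actin. The 11 regions analysed comprised 6 labelled Pdpn-adjacent and 5 labelled SMA-adjacent, from 3 mice in all.

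The regions differed in depth. The 5 SMA-adjacent regions held total counts of 760761 to 3086323, with a median of 2048781. The 6 Pdpn-adjacent regions held 22757 to 2271664, and regions 2, 3 and 11 held 22757, 81760 and 30316. Region 4 held 2271664, and regions 7 and 8 held 225875 and 301401. The edgeR fit gives deeper libraries more weight, most of all for genes of low count. Its log2 fold changes therefore lean on region 4 and can differ from the group means of CPM. In region 2, 17960 of 19965 probes (90.0%) stood at the lowest value of 1, and in region 11 15487 (77.6%) did. The log2 total count was 17.1 ± 2.46 (SD, n = 6) in Pdpn-adjacent and 20.8 ± 0.85 (SD, n = 5) in SMA-adjacent regions (exact permutation p = 0.0173, adjusted p = 0.0866 over 5 measures). The share of counts above background was 24.1% ± 11.8 (SD, n = 6) against 33.8% ± 7.92 (SD, n = 5), with an exact permutation p of 0.149 and an adjusted p of 0.249, and was 6.00% in region 2. The number of probes above the floor, the share of the negative probes and the share of the 10 most abundant probes gave exact permutation adjusted p-values of 0.325, 0.249 and 0.985. Because some regions share a mouse, these p-values can be too small. Across probes, which are not independent replicates, Spearman's rho between SMA-adjacent regions ran from 0.816 to 0.914 and between Pdpn-adjacent regions from 0.0628 to 0.694.

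**Figure D1:**
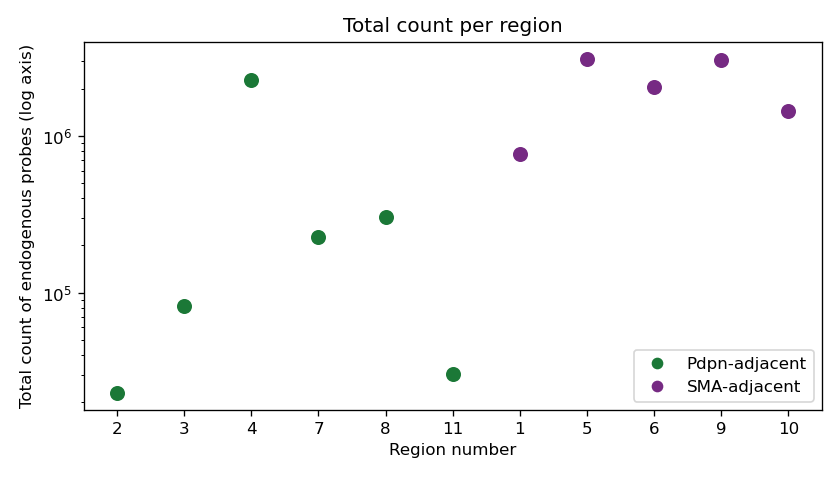
Total count of endogenous probes in each of the 11 regions, on a log axis, with the region number on the horizontal axis and the group as colour. The 5 SMA-adjacent regions lie between 760761 and 3086323, and Pdpn-adjacent regions 2, 3 and 11 lie at 22757, 81760 and 30316.

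Of the genes that defined the segments, Acta2, which encodes smooth muscle actin, was low in Pdpn-adjacent regions, at 141 ± 111 library-scaled counts (CPM; SD, n = 6) against 1098 ± 896 CPM (SD, n = 5) in SMA-adjacent regions. All 6 Pdpn-adjacent regions lay below all 5 SMA-adjacent ones (log2 fold change -2.77 ± 0.70 SE, edgeR adjusted p = 0.205, exact permutation p = 0.00433). Pdpn transcript was near background in every region, at 0.375 to 1.79 times the negative-probe level in Pdpn-adjacent and 1.56 to 1.95 times in SMA-adjacent regions (log2 fold change -0.19 ± 0.28 SE, edgeR adjusted p = 1.00). It was lower in the regions labelled for it, at 36.0 ± 14.0 CPM (SD, n = 6) against 53.2 ± 3.99 CPM (SD, n = 5), with 5 of 6 Pdpn-adjacent regions below every SMA-adjacent one (exact permutation p = 0.0260). Among those 5, regions 2, 3 and 11 held a raw count of 1, the lowest value in the table. Postn transcript was also low, at 0.889 to 4.09 and 1.84 to 5.13 times background (log2 fold change -0.16 ± 0.27 SE, edgeR adjusted p = 1.00). Regions were chosen by the Pdpn and SMA stains and cells by the Postn lineage reporter, so these 3 genes check the labels and are no finding between the groups. Acta2 followed its label. Pdpn transcript did not, but at levels this near background it cannot decide whether the labels hold. These p-values can be too small, since some regions share a mouse. The probes lie on GRCm38.p6 at chromosome 19, 34246192 to 34246226 (Acta2), chromosome 4, 143273991 to 143274025 (Pdpn), and chromosome 3, 54367590 to 54367627 (Postn).

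Few single genes passed the threshold with edgeR. Csn3, which encodes the milk protein kappa-casein, was higher in Pdpn-adjacent regions, at 59.6 ± 22.1 CPM (SD, n = 6) against 34.2 ± 4.15 CPM (SD, n = 5), with 4 of 6 Pdpn-adjacent regions above every SMA-adjacent one. The highest value, 86.4 CPM, came from region 3, with a total count of 81760, where a raw count of 1 stands at 12.3 CPM. It therefore rests on few counts. The Csn3 probe lies on GRCm38.p6 at chromosome 5, 87929839 to 87929874. Csn3 had a log2 fold change of 0.98 ± 0.17 SE (edgeR adjusted p = 0.0413) and levels of 0.952 to 2.63 against 0.938 to 1.19 times background.

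Of 19935 probes tested with edgeR, 2 passed, both higher and 0 lower. DESeq2, with its own size factors, called 1 higher and 16 lower, and limma-voom called 0. At an unadjusted p under 0.05 edgeR gave 566 higher and 636 lower, 1202 in all, where 996.75 would be expected by chance. Csn3 was called in 3 of the 11 fits that left out a region, and was lost without region 4 (log2 fold change 0.58, adjusted p = 0.770) and without regions 4 and 8 (0.52, adjusted p = 0.997), the latter chosen after seeing the data. The count of calls was 53 without SMA-adjacent region 5, 13 without Pdpn-adjacent region 7, and 1 without Pdpn-adjacent region 2, 3 or 11 or SMA-adjacent region 9 or 10. With some regions from the same mouse, the p-values here can be too small.

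**Figure D2:**
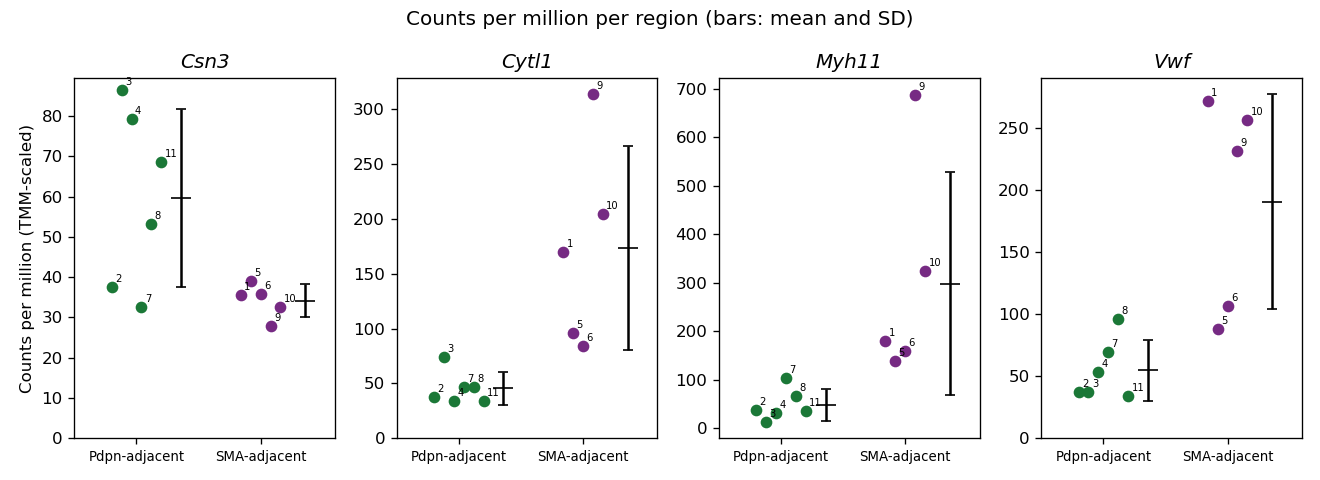
Library-scaled counts (CPM, TMM-scaled) of Csn3, Cytl1, Myh11 and Vwf in each region, with the region number beside each point and black bars for the mean and SD of 6 Pdpn-adjacent and 5 SMA-adjacent regions. Csn3 averages 59.6 against 34.2 and Myh11, which did not pass the test, 47.4 against 298.

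The next genes by p did not pass. On the higher side these were Foxa1, a luminal transcription factor (log2 fold change 0.75 ± 0.14 SE, edgeR adjusted p = 0.0620), Prlr, the prolactin receptor (0.88 ± 0.17 SE, 0.0620), and Slc12a2, a chloride cotransporter (0.91 ± 0.18 SE, 0.0668). On the lower side these were Cytl1, a secreted cytokine-like protein (-2.02 ± 0.37 SE, edgeR adjusted p = 0.0594), Mroh1 (-0.88 ± 0.17 SE, 0.0620), Myh11, the smooth muscle myosin heavy chain (-2.51 ± 0.49 SE, 0.0668), Ogn, a matrix proteoglycan (-1.35 ± 0.27 SE, 0.0702), and Mylk, myosin light chain kinase (-2.16 ± 0.45 SE, 0.0781). Cytl1 averaged 45.5 ± 15.1 CPM (SD, n = 6) against 174 ± 92.9 CPM (SD, n = 5), and Cytl1, Myh11 and Mylk were lower in 6 of 6 Pdpn-adjacent regions than in any SMA-adjacent region. Exact permutation p-values per gene were 0.197 for Prlr and 0.398 for Slc12a2. As some of the regions share a mouse, p-values over regions can be too small.

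Lymphatic and growth factor genes chosen beforehand did not differ past the threshold. Vegfc and Vegfd, which encode lymphatic growth factors, had log2 fold changes of 0.15 ± 0.18 SE and -0.26 ± 0.16 SE (edgeR adjusted p = 1.00 and 0.925). The Ccl21a probe, which matches 5 sites among its near-identical copies and so cannot be assigned to one of them, had -0.08 ± 0.18 SE (edgeR adjusted p = 1.00). The chemokine gene Cxcl12 had -0.39 ± 0.33 SE (edgeR adjusted p = 0.984). Collagen genes Col1a1 and Col4a1 had -1.40 ± 0.60 SE and -0.68 ± 0.31 SE (edgeR adjusted p = 0.763 and 0.793). None of the 13 measured members of the lymphatic endothelial list passed over all genes and 0 adjusted over the list alone (median log2 fold change -0.05, camera adjusted p = 0.465). In either group 0 of them had a median over its regions above 2 times background. The mean level of that list was 1.18 ± 0.23 times background (SD, n = 6) in Pdpn-adjacent and 1.29 ± 0.11 (SD, n = 5) in SMA-adjacent regions, and it was 1.17, 1.17 and 1.42 in the 3 deepest libraries (Pdpn-adjacent region 4, SMA-adjacent regions 5 and 9) and 1.02, 0.924 and 1.23 in the shallow regions 2, 3 and 11. The p-values above can be too small, since some regions share a mouse.

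Smooth muscle genes were lower in Pdpn-adjacent regions. Over all genes 0 of the 14 measured members passed, and adjusted over the list alone 10 were lower, among them Myh11, Mylk, Myl9 and Tagln. Myl9, a myosin light chain, averaged 81.3 ± 45.4 CPM (SD, n = 6) against 397 ± 250 CPM (SD, n = 5), and Tagln, an actin-binding protein, 102 ± 54.6 CPM against 532 ± 406 CPM. The list's median log2 fold change was -0.84 and its matched random lists had a median of -0.10 (percentile 0). Camera called it lower (adjusted p = 7.77e-18), but not with an estimated correlation (adjusted p = 0.0698 with an estimated correlation). Acta2 belongs to this list and its protein was stained to choose the regions, so the list is not independent of how regions were chosen. Without Acta2 the median of the remaining 13 was -0.79. Since some regions come from a shared mouse, these p-values can be too small.

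Luminal epithelial genes were called higher in Pdpn-adjacent regions as a group by camera. Over all genes 1 of the 18 measured members (Csn3) passed, and adjusted over the list alone 15 were higher, including Foxa1, Prlr and Cldn4, a tight junction protein (log2 fold change 0.78 ± 0.16 SE, edgeR adjusted p = 0.0781, exact permutation p = 0.167). The median log2 fold change was 0.71 (percentile 100 of matched lists), and camera called the list higher (adjusted p = 5.66e-20), but not with an estimated correlation (adjusted p = 0.0698 with an estimated correlation). The list's mean level was 2.37 and 2.96 times background in regions 4 and 8 and 1.14 to 1.57 times in the other 9 regions, and between the groups it was 1.73 ± 0.75 (SD, n = 6) against 1.39 ± 0.11 (SD, n = 5; exact permutation p = 0.444, adjusted p = 0.488 over 26 lists). Without regions 4 and 8, an alternative chosen after seeing the data, the median was -0.01 and the camera adjusted p was 0.916. Because some regions share a mouse, these p-values can be too small.

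Skeletal muscle and Schwann cell genes were called higher with the preset correlation, and neither call held in all alternatives. For skeletal muscle, 0 of 13 members passed over all genes and 3 were higher adjusted over the list alone, Myh1, Mylpf and Tnni2, which encode contractile proteins of fast muscle. The median log2 fold change was 1.78 and camera called the list higher (adjusted p = 8.42e-08), but not with an estimated correlation (adjusted p = 0.209 with an estimated correlation), with array weights (0.613), with the negative-probe level as a covariate (0.435) or after background subtraction (0.730). Its mean level was 65.7 and 30.3 times background in regions 3 and 7 and 1.08 to 9.23 times in the other regions, and without those 2 regions, an alternative chosen after seeing the data, the median was -0.98 and the list was called lower (camera adjusted p = 0.000955). Pvalb, a calcium-binding protein of fast muscle, averaged 193 ± 228 CPM (SD, n = 6) against 70.0 ± 53.6 CPM (SD, n = 5). For the 12 genes of Schwann cells and nerve, 3 were higher adjusted over the list alone, among them the transcription factor Sox10 (log2 fold change 0.55 ± 0.20 SE, edgeR adjusted p = 0.673) and the myelin gene Prx (0.41 ± 0.15 SE, 0.694), with exact permutation p-values of 0.647 and 0.675. The median was 0.13 (percentile 97.1, inside the middle 95% of matched lists), and camera called the list higher (adjusted p = 1.68e-05), but not with an estimated correlation (adjusted p = 0.0698 with an estimated correlation), not on quantile-normalized values (0.0533) and not without regions 4 and 8 (0.115). These p-values can be too small, since some regions share a mouse.

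**Figure D3:**
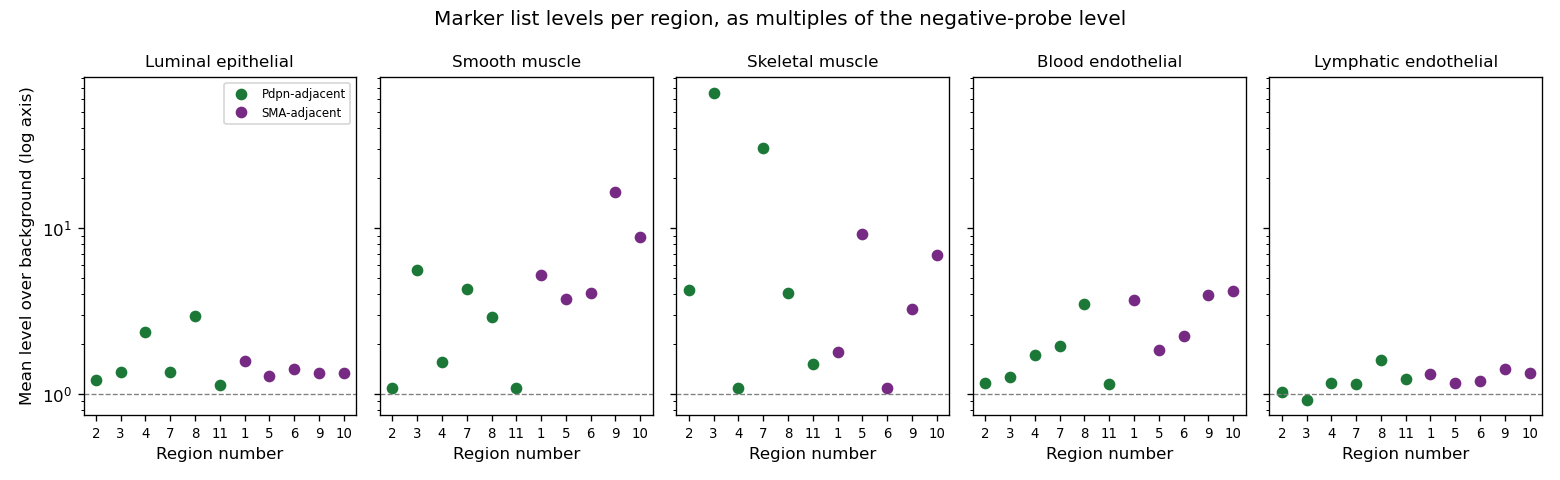
Mean level of 5 marker lists in each region as a multiple of the negative-probe level, on a log axis, with the region number on the horizontal axis and a dashed line at background. Luminal genes reach 2.37 and 2.96 in regions 4 and 8, skeletal muscle genes 65.7 and 30.3 in regions 3 and 7, and lymphatic genes stay between 0.924 and 1.59.

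Fibrillar matrix genes were lower in Pdpn-adjacent regions, and matrix proteases and their inhibitors were lower to an extent within the range of random lists of equal abundance. Of 29 fibrillar matrix genes, 0 passed over all genes and 5 were lower adjusted over the list alone. Among them Bgn, the proteoglycan biglycan, averaged 78.9 ± 38.6 CPM (SD, n = 6) against 224 ± 88.2 CPM (SD, n = 5), Eln, elastin, 79.6 ± 49.5 against 209 ± 88.9 CPM, and Fn1, fibronectin, 43.6 ± 20.5 against 97.3 ± 34.9 CPM. Mfap4, a microfibril protein, had a log2 fold change of -0.81 ± 0.21 SE (edgeR adjusted p = 0.237), but 45.7 ± 20.8 CPM (SD, n = 6) against 49.6 ± 11.5 CPM (SD, n = 5), with 2 of 6 Pdpn-adjacent regions above every SMA-adjacent one (exact permutation p = 0.522). The list's median was -0.43 (percentile 0), with camera adjusted p = 1.26e-19 and adjusted p = 0.0698 with an estimated correlation. Of 21 matrix proteases and inhibitors, 0 passed over all genes and 3 were lower adjusted over the list alone, the protease inhibitors Timp4 (log2 fold change -0.97 ± 0.21 SE, edgeR adjusted p = 0.0934) and Timp2 (-1.33 ± 0.33 SE, 0.179) and the protease Mmp23 (-0.73 ± 0.21 SE, 0.403). Mmp9, a gelatinase, had -0.44 ± 0.18 SE (edgeR adjusted p = 0.761). That list had a median of -0.13 (percentile 3.16, inside the middle 95% of matched lists), camera adjusted p = 2.48e-05 and adjusted p = 0.0936 with an estimated correlation. Of 19 basement membrane genes 0 passed over all genes and 0 adjusted over the list alone (median -0.20, percentile 0.16, camera adjusted p = 8.73e-05, adjusted p = 0.200 with an estimated correlation), with Col18a1 at -0.69 ± 0.23 SE and Lamc1 at -0.50 ± 0.23 SE. Without regions 2, 3 and 11, an alternative chosen after seeing the data, the basement membrane list was not called (camera adjusted p = 0.0509), nor was it after background subtraction (0.0578) or with the share of counts above background as a covariate (0.0883), chosen likewise. With some regions from the same mouse, the p-values here can be too small.

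Genes of transforming growth factor beta signalling were also lower as a group, and those of universal and adventitial fibroblasts were lower to an extent within the range of random lists of equal abundance. Of 18 genes of that pathway, 0 passed over all genes and 2 were lower adjusted over the list alone, Ccn2, a matricellular target gene (log2 fold change -1.42 ± 0.37 SE, edgeR adjusted p = 0.217), and Ltbp4, a latent growth factor binding protein (-1.26 ± 0.41 SE, 0.586). The inhibitor Smad7 had -0.49 ± 0.19 SE (edgeR adjusted p = 0.710). The list's median was -0.19 (percentile 0.06), with camera adjusted p = 0.000349 and adjusted p = 0.184 with an estimated correlation, and it was not called after background subtraction (0.0654), an alternative chosen after seeing the data. Of 17 genes of universal and adventitial fibroblasts, 0 passed over all genes and 0 adjusted over the list alone (median -0.14, percentile 5.34, inside the middle 95% of matched lists, camera adjusted p = 6.50e-05, adjusted p = 0.0936 with an estimated correlation). Its members Pi16 and Cd34 averaged 38.9 ± 11.9 and 75.3 ± 27.5 CPM (SD, n = 6) against 62.2 ± 14.2 and 138 ± 37.6 CPM (SD, n = 5). As some of the regions share a mouse, p-values over regions can be too small.

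Genes of blood vessels, macrophages and mast cells were called lower in Pdpn-adjacent regions by camera, at the preset correlation only. Of 14 blood endothelial genes 0 passed over all genes and 1 was lower adjusted over the list alone, Vwf, which encodes von Willebrand factor, at 54.7 ± 24.5 CPM (SD, n = 6) against 191 ± 86.8 CPM (SD, n = 5). The endothelial adhesion gene Pecam1 averaged 63.7 ± 25.8 CPM against 113 ± 32.8 CPM. The list's median log2 fold change was -0.44 (percentile 0), with camera adjusted p = 1.28e-10 and adjusted p = 0.105 with an estimated correlation. Of 15 macrophage genes 0 passed over all genes and 0 adjusted over the list alone (median -0.19, percentile 0.28, camera adjusted p = 1.17e-06, adjusted p = 0.0698 with an estimated correlation), with the complement gene C1qc at -0.57 ± 0.24 SE and the receptor Csf1r at -0.43 ± 0.21 SE. Of 8 mast cell genes 0 passed over all genes and 3 were lower adjusted over the list alone, the proteases Mcpt4 (log2 fold change -1.22 ± 0.32 SE, edgeR adjusted p = 0.237), Cma1 (-1.01 ± 0.27 SE, 0.256) and Cpa3 (-0.70 ± 0.21 SE, 0.450). That list had a median of -0.23 (percentile 0.36), camera adjusted p = 0.00501 and adjusted p = 0.170 with an estimated correlation, and was not called on quantile-normalized values (0.183), by limma-voom (0.0507) or after background subtraction (0.0654). Of 14 antigen presentation genes 0 passed over all genes and 0 adjusted over the list alone (median -0.20, percentile 5.16, inside the middle 95% of matched lists, camera adjusted p = 2.45e-05, adjusted p = 0.170 with an estimated correlation), with Cd74, the invariant chain, at -1.08 ± 0.40 SE. The antigen presentation list was not called without regions 2, 3 and 11 (camera adjusted p = 0.130), after background subtraction (0.503) or with the share of counts above background as a covariate (0.180), alternatives chosen after seeing the data. The p-values above can be too small, since some regions share a mouse.

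Abundant housekeeping and adipocyte genes were lower in Pdpn-adjacent regions to an extent that random lists of equal abundance shared. Ribosomal protein genes (81 members, 0 past the threshold over all genes and 0 adjusted over the list alone) had a median log2 fold change of -0.31 against -0.27 for matched lists (percentile 21.3, camera adjusted p = 9.59e-15, adjusted p = 0.316 with an estimated correlation). Adipocyte genes (18 members, 0 and 0 adjusted over the list alone) had -0.39 against -0.29 (percentile 13.2, camera adjusted p = 8.22e-08, adjusted p = 0.209 with an estimated correlation), and the lipase gene Pnpla2 averaged 375 ± 363 CPM (SD, n = 6) against 735 ± 280 CPM (SD, n = 5). Oxidative phosphorylation genes (80 members, 0 and 0 adjusted over the list alone) had -0.21 against -0.16 (percentile 3.89, camera adjusted p = 5.65e-10, adjusted p = 0.331 with an estimated correlation), and with the negative-probe level as a covariate their median was 0.07 and the list was called higher (camera adjusted p = 0.0318). Without regions 2, 3 and 11, an alternative chosen after seeing the data, none of these 3 lists was called (camera adjusted p = 0.189 for ribosomal protein, 0.769 for adipocyte and 0.163 for oxidative phosphorylation genes). The 122 genes above 10 times background in SMA-adjacent regions had a median log2 fold change of -0.49 and 90.2% were lower, while genes at or below background there had a median of 0.07. These classes were set by the SMA-adjacent level alone, which by itself favours lower values in the other group. Since some regions come from a shared mouse, these p-values can be too small.

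**Figure D4:**
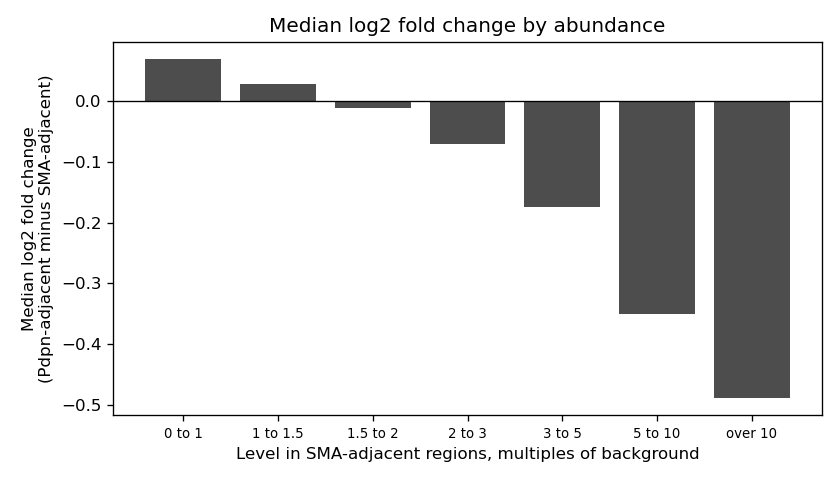
Median log2 fold change (Pdpn-adjacent minus SMA-adjacent) of tested genes, by their level in SMA-adjacent regions in multiples of the negative-probe level. The median goes from 0.07 for genes at or below background to -0.49 for the 122 genes above 10 times background.

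Myoepithelial genes were called higher with the preset correlation. Of 12 members 0 passed over all genes and 1 was higher adjusted over the list alone, the keratin gene Krt5, whose probe lay below background in all SMA-adjacent regions (0.203 to 0.394 times) and at the lowest value of 1 in Pdpn-adjacent regions 2, 3 and 11. The list had a median log2 fold change of 0.16, camera adjusted p = 0.0225 and adjusted p = 0.126 with an estimated correlation. Its mean level was 3.19 times background in Pdpn-adjacent region 11, where Krt14 stood at 16.9 times, and 1.11 to 1.81 times in the other 10 regions. It lost its call in 12 of 18 alternatives, among them the fit without regions 2 and 11 (adjusted p = 0.242), chosen after seeing the data. Because some regions share a mouse, these p-values can be too small.

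The other 8 lists were not called by camera, and none had a member past the threshold over all genes or adjusted over the list alone. Camera adjusted p-values were 0.208 for Wnt signalling, 0.215 for pericytes, 0.275 for vascular growth factors, 0.275 for the interferon response, 0.347 for immediate early and stress genes, 0.628 for proliferation, 0.639 for chemokines and cytokines, and 0.821 for lymphocytes. Median log2 fold changes ran from -0.13 (immediate early and stress genes) to 0.00 (proliferation, 0.0021). For pericytes the median was above 0 (0.0014) while the mean (-0.12) and the test pointed down, and for lymphocytes the median was -0.02 while the mean (0.02) and the test pointed up. In all, camera called 4 of 26 lists higher and 13 lower at the preset correlation, and 0 with an estimated correlation or by fry, whose lowest adjusted p was 0.0919. By the exact permutation test of a list's mean level over background, 0 of 26 lists passed the threshold (lowest adjusted p = 0.161), and 7, all lower, had an unadjusted p under 0.05. These p-values can be too small, since some regions share a mouse.

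The 3 libraries below 100000 counts, all Pdpn-adjacent (regions 2, 3 and 11), set the leading components of variation among regions. These components can therefore not be told apart from depth. The first principal component held 30.4% of the variance of log2 CPM and the second 26.1%. Pdpn-adjacent region 3 lay at 108 along the first and the other regions at -23.0 to 12.1, and Pdpn-adjacent regions 2 and 11 lay at 67.1 and 70.0 along the second and the other regions at -29.0 to -0.839. The groups differed along them with exact permutation p-values of 0.342 and 0.262 (adjusted p = 0.342 for both). On quantile-normalized values the first component held 34.6% of the variance (exact permutation p = 0.0390, adjusted p = 0.0779), and on the most variable genes alone 47.8% (exact permutation p = 0.0584, adjusted p = 0.117). With some regions from the same mouse, the p-values here can be too small.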

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

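The tests against matched random lists, those without regions 2, 3 and 11 or without regions 4 and 8, and that of the smooth muscle level in regions 4 and 8 were chosen only after the results were seen.

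In 7 of 170 groups of regions 1 value stood apart from the rest of its group, where chance would give 8.5 (about 1 group in 20), and 6 of the 7 are given here. Pdpn-adjacent region 3 had the lowest value for Pdpn (12.3 CPM, the others 32.6 to 52.9) and Rpl10l (12.3 CPM, the others 28.0 to 39.9), and both values are a raw count of 1, the lowest value in the table. Region 2 was highest for Cma1 (113 CPM from a raw count of 3, the others 27.5 to 39.9) and lowest for Dpt (37.5 CPM from a raw count of 1, the others 111 to 171). Region 7 was lowest for Cpa3 (9.31 CPM from a raw count of 2, the others 24.7 to 37.5). SMA-adjacent region 9 was lowest for Cdh3 (35.9 CPM, the others 44.8 to 46.6).

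Chance could not be excluded for the count of genes. Of 100 splits of the 11 regions into groups of 6 and 5, drawn from 462 with the real one included, 24 gave 2 or more genes, the real count being 2 and the highest of the others 1775. That highest split set regions 2, 7, 8, 9, 10 and 11 against regions 1, 3, 4, 5 and 6. Of the splits other than the real one 6, the highest included, called more than 100 genes, so the regions hold a structure that their group labels do not follow. The next split, with 1012 genes, set regions 1, 7, 8, 9, 10 and 11 apart, so regions 7 to 11 again lay together. The one after, with 563 genes, set regions 3, 4, 5, 6, 7 and 8 apart. Whether the structure runs with region number was not tested. For the gene lists called by camera at the preset correlation, 2 of the 100 splits, the real one included, gave 17 or more, the real count being 17 and the highest of the others 17, a share under 0.05. Chance can be excluded for that count only as far as regions are independent, and some share a mouse, so the share can be too small. The real split also puts the 3 libraries below 100000 counts in the same group, so a depth difference can raise its count. Without regions 2, 3 and 11, and so with fewer regions, 8 lists were called lower against 13. The other split with 17 set regions 1, 3, 4, 6, 9 and 10 against the rest, and with an estimated correlation camera called 0 lists in the real one. The other splits called 7 lists as a median.

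Smooth muscle genes were lower in Pdpn-adjacent regions, with a median log2 fold change of -0.84. Weaker signal over background would lower all genes of that abundance, but the list's median lay at percentile 0 of 10000 random lists matched on mean CPM, which argues against it as the whole source. The 3 libraries below 100000 counts are argued against as well, since without them the median was -0.84. RNA from muscle cells beside the segments and a difference in the periostin-lineage cells themselves both stay open and were not tested, and the SMA stain by which regions were chosen favours this pattern under either.

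Luminal genes were higher in Pdpn-adjacent regions, with a median log2 fold change of 0.71. Without regions 4 and 8 the median was -0.0125, so the difference rested on those 2 regions, where Krt8 stood at 3.47 and 4.22 and Epcam at 4.46 and 5.11 times background. They were singled out for these levels, so the test shows where the difference lies and not where the RNA came from; epithelial RNA in these regions is a candidate source. A wrong group label on regions 4 and 8 is opposed by the level of smooth muscle genes and stays open for region 8. Of the smooth muscle list, 11 genes were compared, leaving out Tpm2, Ldb3 and Des, which striated muscle also expresses and which reached 35.3, 14.6 and 13.5 times background in region 3, rich in skeletal muscle RNA. In CPM, 10 of the 11 in region 4 and 9 in region 8 lay below every SMA-adjacent region, Acta2, Myh11, Mylk, Myl9 and Tagln among them. Their mean log2 CPM lay 2.32 and 1.53 SMA-adjacent SDs below the SMA-adjacent mean (SMA-adjacent distances -0.837 to 1.59). These genes vary together, so they count as 1 measure, and the distance of -1.53 for region 8 falls short of the bound of 2 set for it. Pdpn-adjacent region 7 lay at -1.43, also with 9 of the 11 below every SMA-adjacent region, so region 8 did not stand apart from its group. Regions 2, 3 and 11 lay at -2.38, -2.66 and -2.49. Whether the nearness of ducts to those lymphatic vessels accounts for it was not tested.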

How the results depend on the processing

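No paired analysis was possible, since the labels do not tie a region to a mouse. Each region number also occurs once, so the groups share no replicate numbers. The alternatives that left out groups of regions, scaled by negative probes, subtracted background or used the share of counts above background were chosen after seeing the data. The cause of the changes was not tested, except where fewer genes or regions entered by construction. Depth limits all of this: 3 of 6 Pdpn-adjacent libraries held under 100000 counts.

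Against 2 genes called by edgeR, 2 higher and 0 lower, the strict filter (at least 10 counts in 9 of 11 libraries, 777 genes) gave 0 (0 higher), upper-quartile scaling 1 (1 higher), quantile normalization with limma 0 (0 higher) and limma-voom 0 (0 higher). The negative-probe level as a covariate gave 11 (9 higher, 2 lower), the region number as a covariate 15 (9 and 6), limma with array weights 6 (1 and 5), DESeq2 17 (1 and 16, with 17008 adjusted p-values not given) and robust spread 8 (5 and 3). Without regions 2 and 11 there was 1 (1 higher), without regions 2, 3 and 11 1 (1 higher), without regions 4 and 8 13 (13 higher) and without regions 3 and 7 14 (14 higher). Negative-probe scaling gave 1 (1 higher), background subtraction in 8 deeper libraries 1 (1 higher, another gene), and the share of counts above background as a covariate 37 (21 and 16). Leaving out 1 region at a time gave 1 to 53 genes, 1 to 12 higher and 0 to 41 lower. The 53 came without SMA-adjacent region 5 and 13 without Pdpn-adjacent region 7.

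Against 4 lists higher and 13 lower, the strict filter gave 1 and 3. Under that filter only the adipocyte, ribosomal, oxidative phosphorylation and skeletal muscle lists kept the 3 members required for a test. The other lists were not tested there, which is no loss of a call. Quantile normalization gave 2 higher, array weights 2 higher, leaving out regions 4 and 8 1 higher, and leaving out regions 2, 3 and 11 8 lower. Background subtraction gave 2 and 6, an estimated correlation 0 and 0, and fry 0 and 0. Leaving out 1 region at a time gave 3 to 4 higher and 13 to 14 lower. The smooth muscle, fibrillar matrix, blood endothelial, macrophage, matrix protease and universal adventitial lists each kept their call and direction in 16 of 18 alternatives. All 16 used the preset correlation of 0.01, and the calls were lost with an estimated correlation and by fry. The estimated correlations of these lists ran from 0.101 (universal adventitial) to 0.529 (blood endothelial), so the 16 share an assumption that the estimates go against. The depth difference in log2 total count ran from -4.48 to -3.15 when 1 region was left out, the share of the top 10 probes from -0.27 to 0.32 points, the share of the negative probes from 0.0633 to 0.137 points, the probes above the floor from -1349 to -564, and the share above background from -13.2 to -6.11 points. The adjusted p of the group difference along component 1 was 0.117 with the most variable genes alone and 0.0779 with quantile normalization, against 0.342, and unadjusted 0.0584 and 0.0390.

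The direction of some values reversed, for lists as read from camera, none of them past the threshold except where said. With the negative-probe level as a covariate the log2 fold change was 0.13 for Pnpla2, 0.10 for Plin1, 0.13 for Cidec, 0.038 for Atp5h and 0.0046 for Ccl21a, and the list medians were 0.13 for adipocytes and 0.072 for oxidative phosphorylation, the latter called higher. With quantile normalization H2-DMa was at 0.12, Vegfc at -0.31 and the lymphocyte list at -0.043. With limma-voom H2-DMa was at 0.075, Ccl21a at 0.13 and the lymphocyte list at 0.092 (its test turned). With array weights Vegfc was at -0.071 and the lymphocyte list at -0.072. Without regions 3 and 7 Postn was at 0.024, Cox6a2 at -0.84, Myh1 at -0.54, Mylpf at -1.50, Tnni2 at -0.98, Pvalb at -1.17, the skeletal muscle list at -0.98 (called lower) and the lymphatic endothelial list at -0.043. Without regions 4 and 8 Fcer1a was at -0.27, Krt15 at -0.12, Sox10 at -0.14, Ccl21a at 0.076 and the chemokine list at 0.076. Without regions 2, 3 and 11 the adipocyte list was at -0.0018. After background subtraction H2-DMa was at 0.11 and the adipocyte, lymphocyte and pericyte lists at 0.061, -0.035 and 0.19. With the share of counts above background as a covariate the ribosomal, immediate early and lymphocyte lists were at 0.051, -0.013 and -0.055.

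Leaving out 1 region at a time also turned the direction of some values, with log2 fold changes from -0.32 to 0.11 for Postn, -0.79 to 0.084 for Cidea, -1.37 to 0.18 for Plvap, -0.16 to 0.37 for Fcer1a, -0.25 to 1.92 for Pvalb, -0.14 to 0.055 for Ccl21a and -0.012 to 0.22 for Vegfc, and list medians from -0.043 to 0.080 for chemokines, -0.24 to 0.037 for immediate early genes and -0.068 to 0.049 for lymphocytes.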

Other observations

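The genes in this part were chosen after their values were seen, and the lists of keratinocyte, sebaceous and haemoglobin genes were written after the leading genes of each region had been looked at.

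Haemoglobin transcripts, abundant in red blood cells, were high in all 5 SMA-adjacent regions and uneven in the others. The mean level of Hba-a1, Hbb-b1 and Hbb-b2, which belong to families of near-identical copies, was 31.3 to 103 times background in SMA-adjacent regions. Among Pdpn-adjacent regions it was 44.0 in region 7, 26.7 in region 8, 4.76 in region 2, 1.58 in region 4, 1.19 in region 11 and 0.875 in region 3. Their log2 fold changes were -2.10 ± 1.18 SE, -2.14 ± 0.92 SE and -2.09 ± 0.65 SE, none past the threshold with edgeR (edgeR adjusted p = 0.911, 0.761 and 0.494, possibly too small because some regions share a mouse), and limma with array weights called Hbb-b1 and Hbb-b2 lower. Region 4, with a total count of 2271664, held Hba-a1 at 2.31 times background, and SMA-adjacent regions held it at 52.6 to 177 times.

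Pdpn-adjacent region 11 differed from the other 10 regions in its leading genes. Elovl4, which encodes an enzyme that elongates very long chain fatty acids, had a raw count of 182 there, 162 times background (95% Poisson interval 139 to 187, which covers counting error only), and was at 1.09 to 1.72 times in SMA-adjacent and 0.952 to 3.00 times in the other Pdpn-adjacent regions. The basal keratin gene Krt14 was at 16.9 (10.2 to 26.4) times background, against 0.857 to 0.981 in SMA-adjacent and 0.375 to 1.46 in the other Pdpn-adjacent regions. Of 9 genes known from sebaceous glands 6 stood above 3 times background in region 11, among them Far2 at 28.5 (19.5 to 40.2) and Krt79 at 17.8 (10.9 to 27.5), and 0 or 1 did in each other region. Of 12 keratinocyte genes 3 did, with Sbsn at 35.6 (25.4 to 48.4), and 0 or 1 in each other region.

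Mgp, a matrix protein that inhibits calcification, Gdf10, a growth factor of the transforming growth factor beta family, and Fmo2, a monooxygenase, were among the 14 genes lower at an edgeR adjusted p under 0.10, none past the threshold. Their log2 fold changes were -2.75 ± 0.58 SE, -1.29 ± 0.27 SE and -1.37 ± 0.29 SE (edgeR adjusted p = 0.0781 for each, possibly too small because some regions share a mouse), and DESeq2 called all 3 lower. Mgp stood at 9.18 to 43.8 times background in SMA-adjacent and 0.952 to 5.39 times in Pdpn-adjacent regions.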
